A study of Mus musculus with 4 samples.

How the data were processed

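A pooled CRISPR knockout screen was run in 293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Cells received the human GeCKO v2 lentiviral guide library, were selected with puromycin, and were stained with RL2, a monoclonal antibody that binds O-linked N-acetylglucosamine (O-GlcNAc) on nuclear and cytosolic proteins. RL2-high cells were then sorted, and the guide sequences integrated in their genomic DNA were amplified by PCR and sequenced. The labels list 4 libraries, 2 called RL2 control and 2 called RL2 positive. An unsorted sample is mentioned in the design for judging library coverage, but the labels do not say whether the control libraries are that sample. The organism field of the labels names the mouse, whereas the cell line, the guide library and the gene symbols are human, and the screen was treated as human.

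The deposited file was 1 table with a row per gene, in the layout of a MAGeCK gene summary, and MAGeCK and the build hg38 are named in the submitters' processing notes. Only the columns for positive selection were in this table. Guide counts, values per library and the ranking for negative selection were not used here. How guides were counted, normalized and filtered, which libraries were set against which, and whether the replicates were pooled are not given in the sources used here. The direction of the comparison was taken from the design, as RL2-positive over control. The depth per library is therefore unknown, and no error across libraries accompanies any deposited value.

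Each row of the authors' table gives, with its column names read by the conventions of MAGeCK, the number of guides of the gene, a robust rank aggregation score, a p-value of that score, a false discovery rate, the rank of the gene by score, the number of its guides within the top share of all ranked guides, and a log fold change. Per the file headers, the score, p-value and rank are for positive selection. A lower score was read as a stronger enrichment, also by the convention of MAGeCK. The deposited log fold change was read as log2, the convention of MAGeCK, because the header states no base. It was also read as the median over the guides of a gene, which the header does not state either, and this was tested. Of the 5-guide rows, the 422 with at least 3 guides in the top share had log2 fold changes of at least 0.35, and the 998 with under 3 had at most 0.59, so 145 rows lay where these overlap. Among rows with a single guide, the guides in the top share began at 0.40 and the others ended at 0.47. In 100000 drawn sets of 5 single guides, 46.1% of the sets with at least 3 guides in the top share had a mean below the lowest value of such rows, and 41.9% of the other sets had a second highest guide above the highest value of theirs. For the median both shares were 0%, so of these 3 readings only the median kept within the observed limits. The comparisons with drawn non-targeting guides rest on it. From the single-guide rows, the top share was between 39.2% and 39.3% of all ranked guides. The deposited false discovery rate differed by at most 2.5e-05 from a Benjamini-Hochberg adjustment of the deposited p-value over all rows.

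The table held 21707 rows and 118056 guides. These were 18912 rows of protein genes, 1795 rows of microRNA genes (names beginning with hsa-) and 1000 non-targeting guides, each a row of its own. Of the protein-gene rows, 16933 had 6 guides. In 35 rows the name was a date, with 24 distinct names, and 11 of these names stood on 22 rows. Such rows stayed in the background and no gene was named from them. Symbols are those of the table, some of them older, such as MGEA5 for OGA. The gene table supplied as a reference was of the mouse and was not used, so no coordinates are given.

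The design fixed before the data were examined foresaw a count model per guide, and this could not be run on a table of gene results. Its stated fallback was used: per-gene scores, p-values and false discovery rates are the authors' own, at a threshold of 0.05 on the false discovery rate, and no test of a single gene was added. The deposited p-values of a list's members were also adjusted by Benjamini-Hochberg over that list alone. A set of 18 gene lists with 547 symbols was fixed before the data were examined, of which 538 had a row. For each list, the median of the deposited log2 fold change was compared with 10000 random lists of as many protein genes, in a two-sided permutation test with Benjamini-Hochberg adjustment over the 18 lists. The smallest two-sided p this can give is 0.0002. Genes were the units of this test and are not replicates, so it says whether a list stood apart from other genes in this table. On simulated lists drawn from the 18912 protein genes, 3.5% of lists of 20 genes with no shift had p under 0.05, against 44.5% with a shift of 0.5 and 93.0% with a shift of 1 on the log2 scale. For lists of 70 genes these shares were 5.5%, 93.0% and 100%. The adjustment over the 18 lists was not part of this simulation, so it does not give the power of the adjusted test.

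Non-targeting guides gave the background. Medians of as many guides as a gene has were drawn 100000 times from the 1000 non-targeting log2 fold changes, and the share of draws as high as the gene was recorded. The number of guides in the top share was compared with a binomial distribution in a chi-square test over genes with 6 guides. Intervals of shares are 95% Wilson intervals and cover counting error over rows only.

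The named genes were chosen by a rule fixed before the data were examined. It takes the 10 genes with at least 3 guides and the smallest p-values, then OGT, OGA and FBXO31, and then up to 4 members of each list by p-value with any member past the threshold. Some genes that this rule takes are not reported here. Its part on depleted genes could not be applied, because the negative selection ranking was not used here. Alternatives were other thresholds, leaving out genes with fewer than 3 guides, ranking by log2 fold change, and median rank in place of median log2 fold change. Ranking by score, restricting the adjustment to protein genes, matching random lists on guides per gene, using the share of guides in the top share, and leaving FBXO31 out of its list were added after seeing the data. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.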

Results

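The screen asked which gene knockouts were more frequent among 293T cells with high RL2 staining. Such staining was taken as a sign of high O-GlcNAc, the single-sugar modification that OGT adds to proteins and OGA removes. The labels list 2 RL2-positive and 2 control libraries, and the data were 1 table of gene results for 18912 protein-gene rows, 1795 microRNA genes and 1000 non-targeting guides. The design says that the screen was done 2 times, without saying whether the transduction was repeated. The depth of the libraries is unknown, and the deposited values carry no error across libraries. The table does not state which libraries it compares, or the direction or base of its log fold changes, which were taken as RL2-positive over control and log2, and a gene's value was read as the median over its guides.

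No gene passed the threshold for enrichment in RL2-high cells. The first 10 genes were SPP1, FAM115A, RNF165, CLPS, CCDC154, TSC2, MFRP, NOD2, DUX2 and hsa-mir-6124, and the lowest false discovery rate in the authors' deposited table (MAGeCK) was 0.861. At an unadjusted p under 0.05 there were 1072 of 21707 rows in the authors' deposited table, where 1085 would be expected with no enrichment. All 6 guides of CLPS, which encodes pancreatic colipase, and all 6 of TSC2, the RHEB-inactivating partner of TSC1 and a brake on mTORC1, lay in the top share, with log2 fold changes of 2.20 and 1.91 in the authors' deposited table. RNF165, a RING-type ubiquitin ligase, and NOD2, an intracellular sensor of bacterial muramyl dipeptide, had 4 of 6 guides in the top share and log2 fold changes of 2.30 and 2.31 there, in the authors' deposited table. SPP1, which encodes the secreted phosphoprotein osteopontin, ranked first in the authors' deposited table (MAGeCK p = 0.000148) with 3 of 6 guides in the top share and a log2 fold change of 0.45.

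Of the rest of the first 10, FAM115A had 4 of 6 guides in the top share and a log2 fold change of 1.12 in the authors' deposited table. CCDC154 and MFRP, a frizzled-related membrane protein, each had 3 of 5 guides there, with 0.45 and 0.76 in the authors' deposited table. DUX2, a member of a repeated double homeobox family and therefore uncertain as a target, had 3 of 5 guides and 2.44, and the microRNA gene hsa-mir-6124 had 3 of 4 guides and 2.50, in the authors' deposited table. Medians of 6 drawn non-targeting guides reached the value of SPP1 in 32.9% of draws and that of FAM115A in 3.06%, whereas they reached that of TSC2 in 0.018%, that of CLPS in 0.002% and those of RNF165 and NOD2 in 0.001% each. These genes were picked as the first of the ranking. Among all genes with 6 guides, the gene itself included, 26.5% were as high as SPP1, 5.06% as FAM115A, 0.130% as TSC2 and 0.0295% as CLPS, and NOD2 and RNF165 were the highest of all. A single non-targeting guide stood at rank 12 of the authors' deposited table, with a log2 fold change of 5.53 and the smallest p of all rows (MAGeCK p = 0.000125).

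Across the whole table, the share of small p-values among protein genes was within counting error of that under no enrichment. Of the 18912 protein-gene rows, 939 had a p under 0.05 in the authors' deposited table, against 945.6 expected, or 4.97% with a 95% Wilson interval of 4.66% to 5.28%. At a p under 0.01 there were 197 rows in the authors' deposited table, against 189.1 expected (1.04%, interval 0.907% to 1.20%). Among microRNA genes 5.52% had a p under 0.05 (interval 4.55% to 6.67%), and among non-targeting guides 3.40% (interval 2.44% to 4.71%), in the authors' deposited table. To pass a false discovery rate of 0.05 without the help of later ranks, the smallest p would have had to be 2.3e-06. It was 54.2 times that and belonged to a non-targeting guide.

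Genes with several guides in the top share were about as frequent as for guides independent of their gene. Of the 16933 protein genes with 6 guides, 71 had all 6 guides in the top share in the authors' deposited table and 579 had 5, against 60.2 and 563.5 expected if guides were independent of their gene. No guide was in the top share for 848 genes, against 866.5 expected. No difference from the binomial distribution was detected (chi-square 4.59 on 5 degrees of freedom, p = 0.468 over genes). The top share is broad, between 39.2% and 39.3% of all guides, so a guide in it need not be enriched. The test over all these genes therefore cannot exclude a small number of genes whose guides were enriched together.

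**Figure D1:**
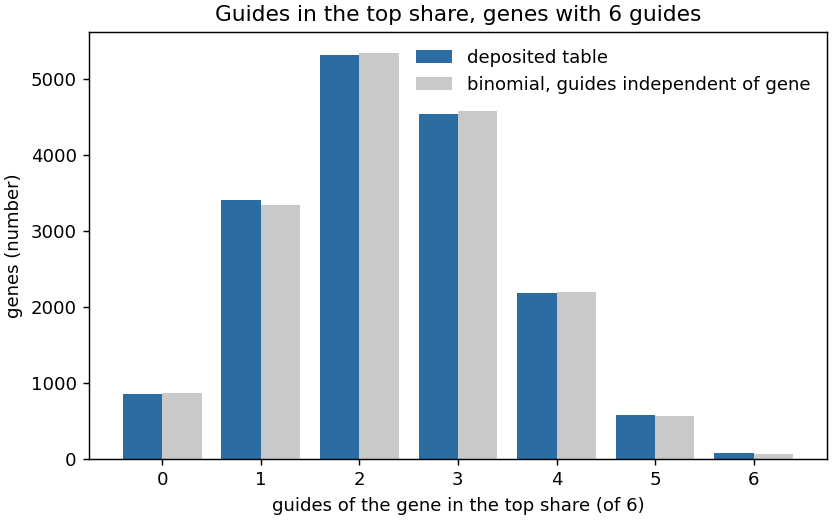
Number of protein genes with 6 guides (vertical axis) by how many of their guides lay in the top share (horizontal axis), in the deposited table (blue) and under a binomial distribution with guides independent of gene (grey). The bars are of similar height at each number, with 71 observed and 60.2 expected genes at 6 of 6 guides.

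Neither of the O-GlcNAc cycling enzymes passed the threshold. OGA, the hydrolase that removes O-GlcNAc (listed as MGEA5), had 5 of 6 guides in the top share and a log2 fold change of 1.45, or 2.73-fold, at rank 986 of the authors' deposited table (MAGeCK p = 0.0482, false discovery rate 0.978). Medians of 6 non-targeting guides were as high in 0.50% of draws, and 1.44% of the genes with 6 guides were. OGT, the transferase that adds O-GlcNAc, had 2 of 6 guides in the top share and a log2 fold change of -0.57 at rank 15035 of the authors' deposited table (MAGeCK p = 0.706), and 86.7% of draws and 64.4% of the genes with 6 guides were as high. The list of these 2 genes had a median of 0.44 (adjusted permutation p = 0.630). Random lists of 2 genes had a wide central range, from -2.48 to 0.97. OGT and OGA act on O-GlcNAc in opposite directions, so opposite shifts would offset each other in the list median. That median therefore cannot decide whether the cycling enzymes stood apart. Adjusted over the list alone, the smaller MAGeCK p was 0.0964, so 0 of 2 passed. MAGeCK p-values here are for enrichment only, so that of OGT cannot show a depletion in RL2-high cells. The difference between OGA and OGT was not tested.

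FBXO31, an F-box substrate receptor of SCF ubiquitin ligases and the subject of the study's title, ranked 778 and did not pass the threshold. It had 3 of 6 guides in the top share and a log2 fold change of 0.32, or 1.25-fold, in the authors' deposited table (MAGeCK p = 0.0380, false discovery rate 0.978). Medians of 6 non-targeting guides were as high in 42.0% of draws, and 31.7% of the genes with 6 guides were. Among the 68 F-box genes measured, 3 had a p under 0.05, against 3.4 expected: FBXO31, FBXO47 with 3 of 6 guides in the top share and 0.50, and FBXO28 with 5 of 6 and 1.20, in the authors' deposited table. FBXO9 followed with 5 of 6 guides and a log2 fold change of 1.15 in the authors' deposited table. The median log2 fold change of the 68 was 0.21, above the central 95% of random lists (-0.46 to 0.17), but it did not pass after adjustment over the 18 lists (permutation p = 0.0222, adjusted p = 0.200). By median rank the same list did pass, at 6371 against a central 95% of 8094 to 13140 for random lists (permutation p = 0.0008, adjusted p = 0.0144), with 43 of 68 members ahead of the median rank of all protein genes. This adjustment covers the 18 lists by median rank alone and does not count the other measures tried. No F-box gene passed after adjustment over the list alone.

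The other parts of the SCF ligase did not stand apart. The 23 genes of the SCF core and of neddylation, the modification that activates cullins, had a median log2 fold change of -0.17 (adjusted permutation p = 0.945), and 1 had a p under 0.05 against 1.15 expected. That gene was UBE2M, the NEDD8-conjugating enzyme, with 4 of 6 guides in the top share and 1.53 in the authors' deposited table. CDC34, the ubiquitin-conjugating enzyme of SCF, had 2 of 6 guides in the top share and 0.33, UBE2D2 had 2 of 6 and -0.33, and DCUN1D1 had 2 of 5 and -0.27, in the authors' deposited table. The 9 genes of the COP9 signalosome, which removes NEDD8 from cullins, had a median of -0.13, and none of them had a p under 0.05. COPS2 stood first of them with 3 of 6 guides and 0.14, before COPS6, GPS1 and COPS4 with 4 of 6 each and 0.64, 0.62 and 0.57, in the authors' deposited table. Of 29 other cullins and adaptors, with a median of -0.30, none had a p under 0.05, and the first were CUL4B with 5 of 6 guides and 0.79 and DCAF15 with 4 of 6 and 0.92 in the authors' deposited table. TCEB2 (-0.49) and KLHL12 (-0.22) followed in the authors' deposited table. The 32 proteasome genes had a median of -0.24 (adjusted permutation p = 0.841). Of the proteasome genes, 2 had a p under 0.05 against 1.6 expected. PSMC2 ranked first of them despite a negative median (2 of 6, -1.43, MAGeCK p = 0.0180) in the authors' deposited table. PSMB7 (MAGeCK p = 0.0324) and PSMB6 followed with 5 of 6 guides each, at 1.30 and 0.93, in the authors' deposited table. PSMA6 (1 of 6, -1.01) came next in the authors' deposited table. No gene of these 4 lists passed after adjustment over its list alone.

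**Figure D2:**
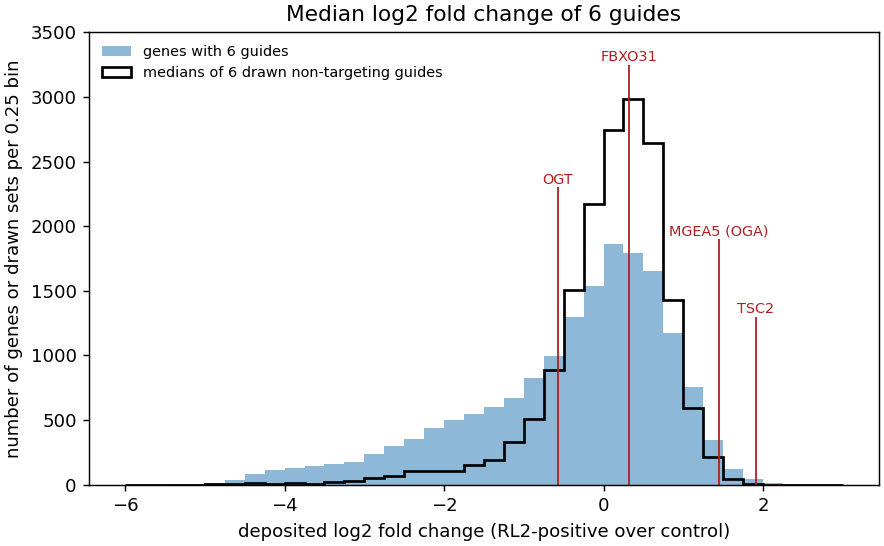
Number of genes with 6 guides (blue) and of as many drawn sets of 6 non-targeting guides (black outline) by deposited log2 fold change, RL2-positive over control (horizontal axis, log2 units). Red lines mark OGT at -0.57, FBXO31 at 0.32, MGEA5 (OGA) at 1.45 and TSC2 at 1.91, and the genes reach further to the left than the non-targeting sets.

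Genes of hexosamine metabolism, which includes the synthesis of UDP-GlcNAc, the sugar donor of OGT, did not stand apart as a list. Not all of them supply this donor, so the list median does not measure its supply. The 15 genes of hexosamine synthesis and salvage had a median log2 fold change of -0.01 (adjusted permutation p = 0.901). NAGK, the kinase that salvages N-acetylglucosamine, had 4 of 6 guides in the top share and 1.64 in the authors' deposited table (MAGeCK p = 0.0194), and was the only member with a p under 0.05, against 0.75 expected. GNPDA2, a glucosamine-6-phosphate deaminase, had 4 of 6 guides and 1.42, GNPNAT1, the acetyltransferase of the pathway, had 3 of 6 and 0.49, and NANP, a sialic acid phosphatase, had 3 of 6 and 0.64, in the authors' deposited table. For glucose and glutamine uptake and use the median of 18 genes was -0.60 (adjusted permutation p = 0.508), none had a p under 0.05, and the first were ENO1 (-1.54), UGP2 (-0.41), PFKP (0.09) and ALDOA (1.05) in the authors' deposited table. For sialylation and N-glycan maturation it was -0.39 (adjusted permutation p = 0.630). There MGAT2, an N-acetylglucosaminyltransferase of the Golgi, had 4 of 6 guides and 1.74 (MAGeCK p = 0.0111), before ALG6 with 0.95 and MGAT1 with 0.17, in the authors' deposited table. No gene of these 3 lists passed after adjustment over its list alone.

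Among 22 known partners and regulators of OGT, 3 had a p under 0.05 against 1.1 expected, and none passed. PPP1R12A, the targeting subunit of myosin phosphatase, had 4 of 6 guides and 1.73 (MAGeCK p = 0.00326), and TET1, a 5-methylcytosine dioxygenase, had 6 of 6 guides and 1.67 (MAGeCK p = 0.00654) in the authors' deposited table. XIAP, an inhibitor of apoptosis with ubiquitin ligase activity, had 4 of 6 guides and 0.85, and MDM2 had 2 of 6 and -2.06, in the authors' deposited table. Adjusted over the list alone the smallest p was 0.0718, and the list's median log2 fold change was -0.14 (adjusted permutation p = 0.968).

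In the list of PI3K, AKT, mTOR and AMPK signalling, TSC2 was the only gene of any of the 18 lists that passed when adjusted over the list alone (adjusted p = 0.00926, from a MAGeCK p of 0.000309 in the authors' deposited table), and over all rows it did not pass. This adjustment does not count the other lists. The 30 genes had a median of -0.20 (adjusted permutation p = 0.901), and 3 had a p under 0.05 against 1.5 expected. The other two were PRKAA1, the catalytic alpha-1 subunit of AMPK, with 2 of 6 guides in the top share and a log2 fold change of -0.00014, and RHEB, the GTPase that TSC2 inactivates, with 1 of 6 and -2.16, in the authors' deposited table. NPRL3, of the GATOR1 complex, had 2 of 6 guides in the top share and -3.67 in the authors' deposited table.

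Cytosolic ribosomal protein genes had a lower median log2 fold change than random lists of genes, while their ranks did not differ detectably. The 78 genes had a median of -0.71, below the central 95% of random lists (-0.44 to 0.15), and this was the only one of 18 lists to pass (permutation p = 0.0014, adjusted p = 0.0252). By median rank, 10020 against a central 95% of 8253 to 12939 for random lists, the list did not pass and lay on the other side of the middle (adjusted permutation p = 0.820). The rank is for enrichment only and need not follow how low a median lies. ATF4, for example, ranked 336 at a log2 fold change of -2.22 in the authors' deposited table. The median rank therefore cannot show or exclude a depletion of the list. By p, 4 members were under 0.05 against 3.9 expected, namely RPL9 (-0.15), RPL23 (1.01), RPS6 (1.26) and RPL39 (-0.81) in the authors' deposited table, and none passed adjusted over the list alone. The 31 nuclear pore genes, whose products include the glycoproteins against which RL2 was raised, had a median of -0.69 (permutation p = 0.0444, adjusted p = 0.266). By the share of their guides in the top share, 28.1% against a central 95% of 31.9% to 46.3% for random lists, a measure added after seeing the data, they did pass (adjusted permutation p = 0.0396). None of these genes had a p under 0.05, and the first were TMEM48 with 3 of 4 guides and 1.62, NUP205 with 0.43, NUP214 with -0.07 and TPR with -0.85 in the authors' deposited table. The 34 core spliceosome genes had a median of -0.53 (adjusted permutation p = 0.387). By the share of guides in the top share, they (32.1%) and the genes of the response to Cas9 breaks (30.5%) also lay just below their random ranges. The F-box genes (44.1%) lay just above theirs. None of these lists passed by that share (adjusted permutation p = 0.212 each). SF3B1 (0.34) was the only spliceosome gene with a p under 0.05, before SRSF1 (0.72), SNRNP200 (0.84) and SF3B2 (0.32), in the authors' deposited table.

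The 4 lists that remain did not pass either. Genes of the unfolded protein and integrated stress responses had a median of 0.25 over 15 genes (adjusted permutation p = 0.559). There ATF4, the main transcription factor of the integrated stress response, ranked first of the list and alone had a p under 0.05, against 0.75 expected. It had 1 of 6 guides in the top share and -2.22, with a MAGeCK p of 0.0158, in the authors' deposited table. The eIF2-alpha kinases EIF2AK3, EIF2AK4 and EIF2AK1 followed with 0.74, 0.95 and 1.01 in the authors' deposited table. The 19 growth suppressors had a median of 0.13 (adjusted permutation p = 0.630), with LATS2 at 1.53, LATS1 at 0.87 and CDKN1A at 0.46 in the authors' deposited table. The 22 genes of the response to Cas9 breaks had a median of -0.74 (adjusted permutation p = 0.320), and the first, ATR, BRCA2, XRCC4 and CHEK1, had -0.05, 0.54, -0.23 and -0.89 in the authors' deposited table. Olfactory receptors, which this line is not expected to express, had a median of -0.29 over 71 genes (adjusted permutation p = 0.630), with 3 members under a p of 0.05 against 3.55 expected. These were OR2G2 (-0.19), OR2AK2 (1.32) and OR1G1 (1.59), and OR2B11 (0.07) followed, in the authors' deposited table. Over all 18 lists, 24 of 538 genes had a p under 0.05, against 26.9 expected.

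**Figure D3:**
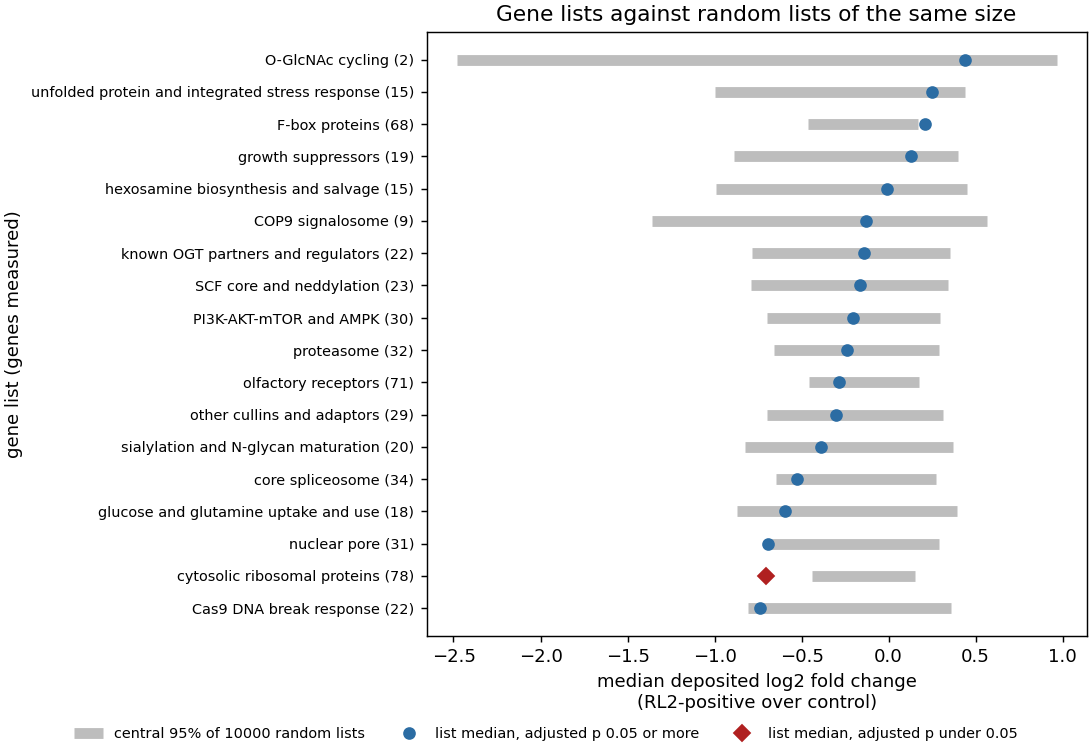
Median over genes of the deposited log2 fold change, RL2-positive over control (horizontal axis, log2 units), for each of 18 gene lists with the number of genes measured in brackets (vertical axis). Grey bars span the central 95% of 10000 random lists of the same size, and the red diamond marks the ribosomal proteins, at -0.71, the only list with an adjusted p under 0.05.

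Non-targeting guides had a median log2 fold change of 0.23 and a wide spread in the authors' deposited table, from -6.71 to 5.53. Sets of 6 drawn from them had a median of 0.21 and a central 95% of -1.96 to 1.16, which is the scatter of a gene's value when its guides have no target. Genes with 6 guides had a median of -0.11 in the authors' deposited table, and 13.3% of them lay below this range and 4.39% above it. MicroRNA genes had a median of -0.04 in the authors' deposited table, and 41.2% of their guides were in the top share, against 39.1% for protein genes and 43.6% for non-targeting guides.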

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

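No paired analysis was possible because the deposited table holds no values per library, and for the same reason no library could be left out, no other normalization or count filter be tried, and the tests on guides (camera, other values of alpha, a guide z-score) were not run. The count of enriched genes was 0 at a false discovery rate of 0.05, of 0.25, with genes of fewer than 3 guides left out, and over protein genes only. At an unadjusted p under 0.01 there were 225 rows of all kinds, 6 of them non-targeting guides, where 217.1 are expected. Among the 20390 genes with at least 3 guides, ranking by log2 fold change kept 35 of the first 100 genes by p. Unrelated rankings would share 0.49, but both rankings come from the same guides, so an overlap above this says little. Ranking by score kept 96, which also says little, because the p-value is that of the score. The number of lists past the threshold was 1 in each setting, but not the same list. The ribosomal proteins passed by median log2 fold change, also with random lists matched on guides and with genes of fewer than 3 guides left out. They did not pass by median rank, which at 10020 lay on the other side of the middle but inside the range of random lists (8253 to 12939). Nor did they pass by the share of guides in the top share (37.1%). By that share the nuclear pore genes passed instead, with 28.1% of guides against a central 95% of 31.9% to 46.3% for random lists (adjusted permutation p = 0.0396). By median rank the F-box genes passed (6371). Without FBXO31 the F-box median was 0.14 in place of 0.21 (adjusted permutation p = 0.384). Over its alternatives the adjusted permutation p ran from 0.0288 to 0.820 for the ribosomal proteins, from 0.0144 to 0.384 for the F-box genes and from 0.0396 to 0.374 for the nuclear pore genes. The cause of these differences was not tested. Among all alternatives for single lists, 69 values kept their side of the threshold. With the depth unknown, a gene below the threshold is one not detected by this table, not one shown to have no effect. Ranking by score, the adjustment over protein genes only, the matched random lists, the share of guides in the top share and the list without FBXO31 were chosen after seeing the data.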

Other observations

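Of the tests below, those on the number of guides, on needed genes, on the scatter of targeting guides and on genes needed for growth were chosen after the result was seen. The genes with all 6 guides in the top share were also picked after their values were seen. After CLPS and TSC2, the best ranked of these 71 genes were CHTF18, which acts in sister chromatid cohesion, at 1.36, LRRC24 at 1.56, DERA, a deoxyribose-phosphate aldolase, at 1.31, OPRD1, the delta opioid receptor, at 1.64, SPINT4 at 1.88 and the histone deacetylase HDAC1 at 1.33 on the log2 scale, in the authors' deposited table. At the other extreme, BATF2 and FAM171A2 each stood among the first 100 genes with 1 of 5 guides in the top share and log2 fold changes of -0.11 and -0.33, and hsa-mir-1289-2 with 1 of 4 and -3.75, in the authors' deposited table. Of those 100 genes, 24 had all guides in the top share, 26 had no more than 50% of them there, and 14 had a log2 fold change below 0. MicroRNA genes made up 11 of the 100, against 8.24 by chance among genes with at least 3 guides, from which the 100 were taken. They were led after hsa-mir-6124 by hsa-mir-148b (1.42) and hsa-mir-6858 (2.44) in the authors' deposited table.

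Genes with 6 guides had a lower median log2 fold change than non-targeting guides. The number of guides behind each value was excluded, since as many drawn sets of 6 non-targeting guides had medians of 0.196 to 0.217 (central 95%), against -0.11 for genes. Loss of cells lacking a needed gene was excluded as the whole cause, since olfactory receptor genes lay at -0.29, below 0.028 to 0.369 for drawn lists of as many guides. A wider scatter to both sides around the same centre is argued against as the whole cause. The top share begins above the non-targeting median, so such scatter would raise the share of guides in it. The top share held 39.1% of the guides of these genes, below the 95% Wilson interval of non-targeting guides (40.6% to 46.7%). Scatter that grew mainly downward, or that lowered the centre, was not tested. The 122 targeting rows with a single guide did have a wider interquartile range (by 0.873, permutation p = 0.0170), but they need not represent the other genes, and guide abundance, Cas9 cutting and any biological explanation were not tested.

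Ribosomal protein genes had a lower median log2 fold change than other genes, while their ranks did not differ detectably. The rank is for enrichment only, so it is no check on a lower median. Of the 78, 16 (20.5%) lay in the lowest 10% of genes, above the central 95% of random lists (3.85% to 16.7%), and 8 (10.3%) in the highest 10%, inside that range. Whether their guides scattered more widely in both directions stays open, because the share in the highest 10% is neither raised nor lowered beyond chance. Loss of cells lacking a gene needed for growth also stays open: the 97 proteasome, spliceosome and nuclear pore genes, pooled after their medians were seen, had a median of -0.48 (central 95% of random lists -0.41 to 0.14, permutation p = 0.0174). By median log2 fold change, only the nuclear pore list (-0.69) lay below its random range on its own, while the spliceosome (-0.53) and the proteasome (-0.24, permutation p = 0.608) did not. By the share of guides in the top share, the spliceosome (32.1%) also lay just below its range (32.5% to 46.0%), and the proteasome (37.2%) did not.

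F-box genes ranked nearer the top than other genes, though their log2 fold change did not pass. The median rank of the 67 others was 6765, but leaving out any 1 member could not have brought it beyond 6765, so this says nothing of the part FBXO31 has in it. That the list reflects several SCF receptors acting on O-GlcNAc was not tested. The SCF core and neddylation genes, on which SCF receptors depend, did not stand apart detectably (median rank 12776, adjusted permutation p = 0.683). This cannot decide the question, because a list of 23 genes can miss a shift. In the simulation by median log2 fold change, a shift of 0.5 gave a permutation p under 0.05 in 44.5% of lists of 20 genes.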
